A study of Mus musculus with 19 samples.

How the data were processed

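Bulk RNA sequencing of cell pellets from bronchoalveolar lavage, the cells rinsed from the airspaces of the lung, was analysed in 19 mice. The labels name the cells alveolar macrophages, the resident phagocytes of the airspace, and describe no sort or gate. The mice were female, 7 to 8 weeks old, and either wild type (C57Bl/6J) or ICAM-1 null. The background of the null line, and whether the wild type mice were littermates, are not given in the sources used here. Loss of ICAM-1 therefore cannot be told apart from other differences between the lines in the genotype and interaction tests. ICAM-1 is a surface adhesion molecule bound by leukocyte integrins. Per the labels' protocols, exposed mice were given 100 µL of Staphylococcus aureus bioparticles at 2.27 mg/mL into the oropharynx under isoflurane and were lavaged 1 h later. The bioparticles carry pHrodo, a dye whose fluorescence increases in acid compartments. Lavage fluid was phosphate-buffered saline with 2 mM EDTA. Whether naive mice received a vehicle or the anaesthetic is not given in the sources used here.

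Per the labels' protocols, libraries were made by poly(A) selection and sequenced as pairs of 150 bases, with 20 M reads planned per library. The submitters' processing notes name STAR, StringTie version 2 and the mouse build GRCm39, and gene coordinates below are those of the deposited tables on that build. The strand setting and the options of the counting step are not given in the sources used here, so overlapping and antisense genes and near-identical copies may share reads. The deposited tables held estimated counts, as whole numbers, and TPM for 56941 genes in each of the 19 libraries. The estimated counts were not scaled for depth by the authors. Among low values, counts of 1 were the most frequent above 0, with another peak at 3 to 4. With totals above the planned reads, 1 sequenced fragment was taken as worth about 4 counts, which is an assumption. The TPM values were scaled by the authors to the same sum in each library. A reference genome of an older build was not used here.

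Total estimated counts ranged from 32.8 to 80.3 M per library. Wild type naive libraries 1, 2 and 3 held 32.8, 37.0 and 41.0 M, and wild type naive library 4 held 80.3 M. The ranges were 59.8 to 78.8 M in naive null, 42.6 to 61.0 M in exposed wild type and 57.0 to 66.3 M in exposed null libraries. A group at 0 counts in every library was given a floor of 3 fragments (12 counts) per library, and a fold against it is stated as a lower bound that covers counting error only.

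The genotype and treatment labels gave 4 groups: wild type naive (n = 4), ICAM-1 null naive (n = 5), wild type exposed (n = 5) and ICAM-1 null exposed (n = 5). The 5 tests were exposed against naive in each genotype, null against wild type in naive and in exposed mice, and the interaction, which is the response of null mice minus that of wild type mice. Estimated counts, already whole, were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test, two-sided, with all 19 libraries in a single model, TMM scaling and the filterByExpr defaults (a minimum count of 10 and a total of 15). This left 20501 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene is said to rise, fall or differ at an adjusted p under 0.05. Values written as ± are SDs of TPM, SE is the standard error of the log2 fold change, and adjusted p-values without another name are those of edgeR.

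The groups, the tests, 28 gene lists, the rule for the genes named and the alternatives first listed were fixed before the data were examined. Lists with at least 5 tested members were tested with camera on voom values (limma 3.58.1), with a preset correlation between genes of 0.01 and, as an alternative, a correlation estimated from the data. Each list's adjusted p is over the 27 lists tested. The list of eosinophil and mast cell markers had 4 members that passed the filter and was not tested. Beside calls over all genes, calls were counted with p adjusted over the list alone. Genes were named if they were among the 10 that rose most or the 10 that fell most, with an adjusted p under 0.05, at least 1 TPM in the higher group and no overlap between the libraries of both groups (not required for the interaction), or among the 4 members of a list with the smallest adjusted p. Predicted genes were not named, and the text names 122 of the genes that the rule gave. A gene withheld from this text is not reported here.

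No pair of libraries within a group held identical counts. On counts divided by 4, the lowest chi-square per gene between 2 libraries of a group was 3.69, against about 1 from sampling alone under that assumption, so each library was counted as 1 replicate. The labels number the mice within each group and do not say that a number marks a shared litter or day, so p-values measure the spread between the mice sampled. The method was tested on simulated counts drawn from the measured means, depths and dispersions, with 200 changed genes per comparison. For genotype in exposed mice it recovered 45% of genes changed 2-fold and 66% of genes changed 4-fold, with 3 false calls among 19594 genes. For exposure in wild type mice it recovered 59% and 64%, with 8 false calls among 19554 genes. For the interaction it recovered 50% and 61%, with 5 false calls among 19606 genes. The changed genes went up and down in equal number around 1 common profile. The false calls therefore do not test the scaling where a large share of genes changes, as on exposure.

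The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter and a stricter filter (50 counts in 4 libraries), a minimum absolute log2 fold change of 1, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), limma-voom with sample weights, only the libraries compared, a replicate block, covariates for neutrophil and lymphocyte RNA, and leaving out each library in turn. Further alternatives were added after the data were seen: counts divided by 4, thinning to the smallest library total on counts divided by 4 (2 choices together), leaving out wild type naive libraries 1, 2 and 3, leaving out 3 exposed libraries that stood apart on the principal components 3 and 4, and covariates for epithelial and red cell RNA.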

Results

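The series measured gene expression in lavage cells of wild type and ICAM-1 null mice, without exposure and 1 h after aspiration of S. aureus bioparticles, in 4 groups of 4 or 5 mice (19 libraries). Total estimated counts were 32.8 to 80.3 M per library. The first principal component of the 2000 most variable genes held 46.2% of the variance and separated exposed from naive libraries. The second held 11.1% and separated wild type libraries (17.4 to 34.2) from null libraries (-29.2 to -19.7).

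The targeted gene was examined first. Icam1 (ENSMUSG00000037405.9, chromosome 9, 20927281 to 20940113) stood at 74.6 ± 10.7 TPM in wild type naive libraries (n = 4) and at 8.13 ± 2.63 TPM in null naive libraries (n = 5), a log2 fold change of -3.13 (SE 0.19, adjusted p = 1.6e-10). After exposure it stood at 899 ± 155 TPM in wild type (n = 5) and at 10.8 ± 1.59 TPM in null mice (n = 5), a log2 fold change of -6.34 (SE 0.21, adjusted p = 7.5e-15). Every null library lay below every wild type library, with 4.88 to 13.2 TPM against 63.8 to 1079 TPM. Icam1 rose on exposure by a log2 fold change of 3.97 (SE 0.20) in wild type and 0.75 (SE 0.17, adjusted p = 0.0012) in null mice. Between 480 and 1186 estimated counts of Icam1 remained in each naive null library.

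**Figure D1:**
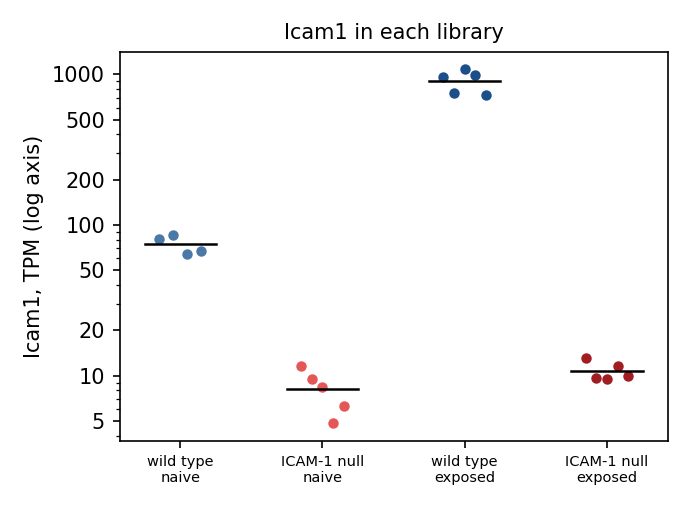
Icam1 in TPM, on a log axis, in each of the 19 libraries by group; points are libraries and bars are group means. Null libraries sit between 4.88 and 13.2 TPM, naive wild type libraries between 63.8 and 85.9 TPM and exposed wild type libraries between 722.5 and 1079 TPM.

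The comparison of exposed with naive wild type mice asked how lavage cells respond to bacterial particles within 1 h. Inflammatory cytokine and chemokine transcripts showed large rises. Tnf (chromosome 17, 35418357 to 35420983) went from 53.0 ± 12.2 to 8822 ± 1310 TPM (log2 fold change 7.76, SE 0.23, adjusted p = 3.0e-16). Il1b went from 18.2 ± 4.73 to 2864 ± 514 TPM. The neutrophil chemoattractants Cxcl1 and Cxcl3 rose by log2 fold changes of 8.93 (SE 0.40) and 8.02 (SE 0.25). Il23a, a cytokine subunit, rose by 8.54 (SE 0.51). Of 34 cytokine genes tested, 30 rose, 0 fell and 4 did not pass (31 rose adjusted over the list alone). Camera gave this list an adjusted p = 2.1e-20, and an adjusted p = 0.028 with an estimated correlation.

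The regulators of this response rose with it. All 27 tested NF-kB components and feedback genes rose, also when adjusted over the list alone (adjusted p = 2.0e-38, and adjusted p = 0.0092 with an estimated correlation). Nfkbiz, which encodes an atypical inhibitor protein of the IkB family, went from 7.48 ± 2.07 to 735 ± 92.7 TPM. Among 33 immediate-early genes, 29 rose, 3 fell and 1 did not pass (29 and 4 adjusted over the list alone; adjusted p = 3.6e-19, and adjusted p = 0.017 with an estimated correlation). Junb, a subunit of AP-1, rose by a log2 fold change of 4.08 (SE 0.12), Atf3 by 4.14 (SE 0.16) and Gadd45b by 6.04 (SE 0.15). The genes that fell most included Hhex, a homeobox transcription factor (72.0 ± 10.6 to 8.04 ± 2.86 TPM), and Bmf, a pro-apoptotic BH3-only gene (52.0 ± 3.25 to 6.71 ± 3.02 TPM). Muc6 (-3.18, SE 0.31), a mucin, and Adra2a (-2.69, SE 0.51), an adrenergic receptor, were lower as well.

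Sensing and uptake genes moved in both directions. Among 28 genes of TLR and inflammasome sensing, 15 rose, 6 fell and 7 did not pass (15 and 7 adjusted over the list alone). Camera gave an adjusted p = 1.0e-04, and an adjusted p = 0.082 with an estimated correlation. Cd14, a co-receptor for bacterial products, rose from 96.7 ± 6.49 to 903 ± 79.1 TPM. The inflammasome sensor Nlrp3 rose by a log2 fold change of 4.78 (SE 0.13) and the receptor Tlr2 by 3.20 (SE 0.11). Among 31 phagocytic and scavenger receptors, 19 rose, 5 fell and 7 did not pass (20 and 7 adjusted over the list alone; adjusted p = 8.1e-04, and adjusted p = 0.14 with an estimated correlation). Clec4e, a C-type lectin receptor, rose by a log2 fold change of 6.16 (SE 0.17) and the complement receptor C5ar1 by 1.90 (SE 0.09). Among 40 phagosome and lysosome genes, 21 rose, 1 fell and 18 did not pass (21 and 1 adjusted over the list alone; adjusted p = 3.3e-06, and adjusted p = 0.13 with an estimated correlation), and the median log2 fold change of 0.19 became -0.19 on the log2(TPM + 1) scale.

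NRF2 targets and metallothioneins had 16 of 24 members higher, 2 lower and 6 not passing (17 and 2 adjusted over the list alone; adjusted p = 5.3e-08, and adjusted p = 0.017 with an estimated correlation). Slc7a11, the cystine transporter, went from 3.13 ± 0.69 to 159 ± 18.6 TPM, and Srxn1 rose by a log2 fold change of 2.74 (SE 0.10). Cholesterol synthesis had 16 of 25 members higher, 2 lower and 7 not passing (16 and 2 adjusted over the list alone; adjusted p = 3.4e-06, and adjusted p = 0.14 with an estimated correlation). Insig1, a sterol-responsive gene, rose by 2.27 (SE 0.12). Glycolysis and HIF-1 targets rose at 14 of 27 genes and fell at 2, with 11 not passing (15 and 2 adjusted over the list alone; adjusted p = 1.9e-04, and adjusted p = 0.077 with an estimated correlation). Among them Hk2, a hexokinase, rose by 2.10 (SE 0.14). Heat shock and unfolded protein response genes rose at 15 of 23 and fell at 2, with 6 not passing (17 and 2 adjusted over the list alone; adjusted p = 3.3e-06, and adjusted p = 0.094 with an estimated correlation). Atf4, a stress response factor, rose by 1.36 (SE 0.08). Lipid handling genes went both ways, 9 up and 9 down of 30 with 12 not passing (9 and 10 adjusted over the list alone; adjusted p = 0.99), with a median of 0.07 that became -0.30 on the log2(TPM + 1) scale. Acod1, which makes itaconate, went from 1.72 ± 1.44 to 42.9 ± 7.47 TPM. Fabp4, a fatty acid binding protein, rose by 2.72 (SE 0.20) and Angptl4, a lipoprotein lipase inhibitor, fell by 2.56 on the log2 scale (SE 0.30).

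Of 15 MHC class II and co-stimulation genes, 11 rose, 2 fell and 2 did not pass (11 and 2 adjusted over the list alone; adjusted p = 3.3e-05, and adjusted p = 0.13 with an estimated correlation). The members named are co-stimulatory or activation markers, Cd83 (3.93, SE 0.15) and Cd86 (2.64, SE 0.23). Interferon-stimulated genes rose at 10 of 37 and fell at 4, with 23 not passing (10 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.19). Its members Irf1 and Gbp5 rose by 3.16 (SE 0.16) and 1.89 (SE 0.27). Alveolar macrophage identity genes rose at 16 of 30 and fell at 5, with 9 not passing (16 and 5 adjusted over the list alone; adjusted p = 0.0054, and adjusted p = 0.13 with an estimated correlation), and had a median of 0.32 that became -0.07 on the log2(TPM + 1) scale. Adhesion partners and cytoskeletal linkers of ICAM-1 rose at 19 of 29 and fell at 3, with 7 not passing (19 and 3 adjusted over the list alone; adjusted p = 1.3e-04, and adjusted p = 0.13 with an estimated correlation). Cell cycle genes (10 up and 2 down of 34, the same adjusted over the list alone; adjusted p = 0.125) and NADPH oxidase genes (4 up and 1 down of 10, the same adjusted over the list alone; adjusted p = 0.0903) did not pass, and their medians of 0.13 and 0.10 became -0.17 and -0.27 on the log2(TPM + 1) scale. Neither did genes beside Icam1 (10 up and 14 down of 37, the same adjusted over the list alone; adjusted p = 0.32) or known strain differences (7 up and 8 down of 25, the same adjusted over the list alone; adjusted p = 0.82).

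Markers of other cells were higher in exposed wild type libraries. Airway and alveolar epithelial markers rose at 20 of 25, with 0 lower and 5 not passing (21 and 2 adjusted over the list alone; adjusted p = 3.3e-05, and adjusted p = 0.13 with an estimated correlation). Scgb1a1, the club cell secretory protein, went from 247 ± 41.5 to 1266 ± 735 TPM. Erythroid and platelet markers rose at 5 of 9 and fell at 0, with 4 not passing (5 adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.21 with an estimated correlation). Hbb-bs, a beta globin, went from 62.8 ± 46 to 418 ± 280 TPM. Neutrophil markers rose at 9 of 14 and fell at 1, with 4 not passing (9 and 1 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.13 with an estimated correlation). Among these, Trem1, a receptor that also responds to activation in macrophages, rose by a log2 fold change of 2.74 (SE 0.15). The G-CSF receptor gene Csf3r fell by 0.55 on the log2 scale (SE 0.08). Monocyte and interstitial macrophage markers rose at 10 of 19 with 0 lower and 9 not passing (10 adjusted over the list alone; adjusted p = 0.0025, and adjusted p = 0.028 with an estimated correlation). C1qb, a complement component, went from 0.80 ± 0.32 to 4.64 ± 2.27 TPM. T and NK cell markers rose at 10 of 20 and fell at 1 (the same adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.14 with an estimated correlation). Dendritic cell markers rose at 7 of 13 (7 adjusted over the list alone; adjusted p = 0.0042, and adjusted p = 0.14 with an estimated correlation), and endothelial and stromal markers at 8 of 18 (8 adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.185 with an estimated correlation), with 0 lower in either list. None of 8 B cell markers passed, also adjusted over the list alone (adjusted p = 0.82).

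In all, 8245 of 20501 genes differed, 4111 higher and 4134 lower, 3298 of them with an absolute log2 fold change of at least 1. Among the genes with the largest rises, 5 were at 0 counts in every wild type naive library. They were the epithelial genes Krt13 (at least 28.3-fold higher), Psca (at least 22.3-fold) and Cnfn (at least 9.97-fold), the interferon-inducible Ifi202b (at least 7.67-fold) and the peptide hormone gene Adm (at least 6.35-fold). On the log2(TPM + 1) scale the median of all genes moved to -0.35 and the split became 1728 higher and 7659 lower (18.4% higher against 49.9%), so small changes are relative to the scaling. Without wild type naive libraries 1, 2 and 3, which leaves a single wild type naive library with the highest Hbb-bs of its group, 4253 genes differed and Hbb-bs (2.02) and Hba-a1 (2.19) no longer passed. Covariates for epithelial and red cell RNA left 2500 genes and covariates for neutrophil and lymphocyte RNA 1481. With the former and the latter covariates no call remained for Bmf (log2 fold changes -1.68 and -1.36), Adra2a (-3.26 and -1.54), Gbp5 (1.38 and 0.60), C1qb (1.95 and 1.41), Hba-a1 (-0.29 and 0.92) and Hbb-bs (-0.51 and 0.85), which are part of the former covariates, nor with the latter for Angptl4 (-1.73). Both sets of covariates followed exposure itself. In wild type, epithelial list levels were at most 2.96 log2 CPM in naive and at least 3.71 in exposed libraries. Neutrophil list levels were at most 1.13 and at least 1.87. Cell mix, lost power and adjustment for the response itself thus cannot be told apart in these losses.

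**Figure D2:**
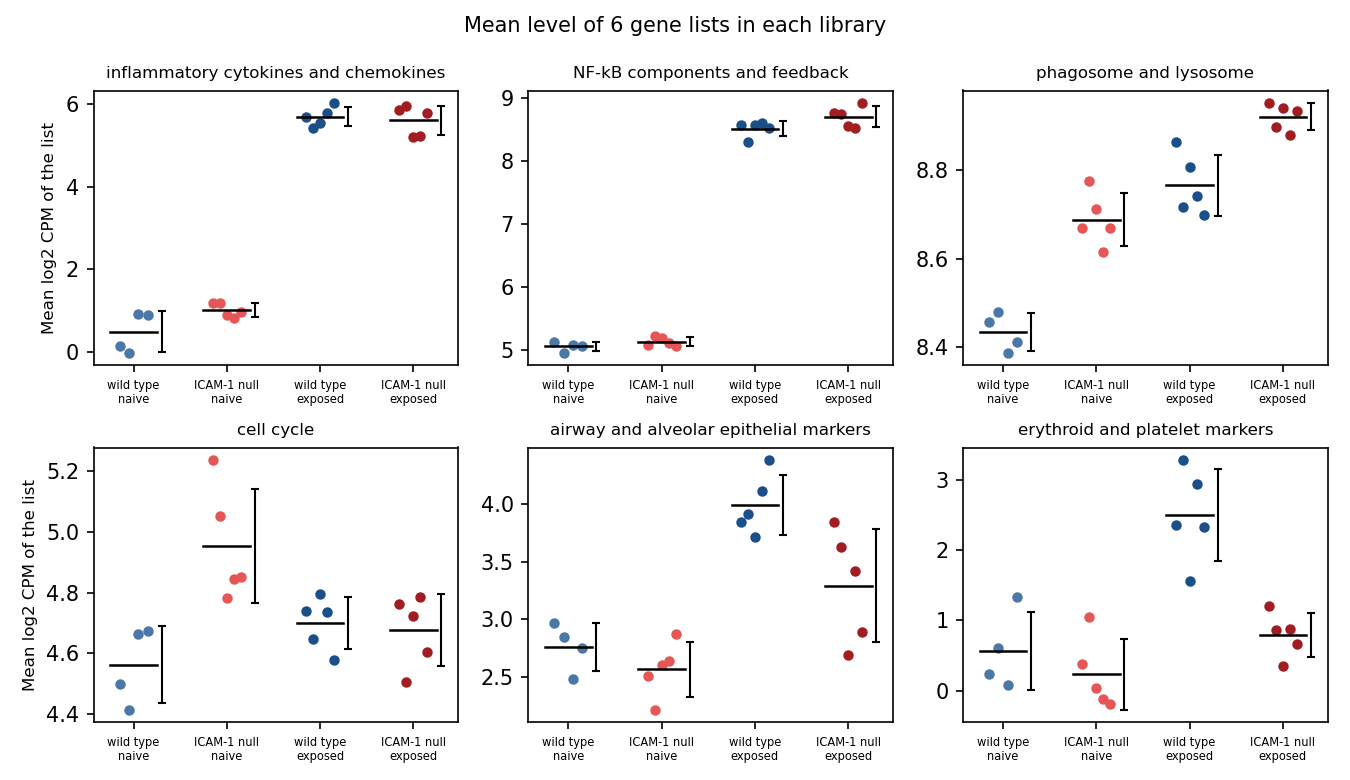
Mean log2 CPM of 6 gene lists in each library by group; points are libraries, horizontal bars are group means and vertical bars are SDs. Cytokines went from a mean of 0.49 to 5.69 on exposure in wild type and from 1.02 to 5.60 in null mice, while erythroid and platelet markers stood at 2.50 in exposed wild type and 0.79 in exposed null libraries.

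The same comparison in ICAM-1 null mice gave a response of the same kind. Tnf went from 72.2 ± 8.73 to 7775 ± 1670 TPM (log2 fold change 7.10, SE 0.20, adjusted p = 7.9e-17), and Il1b from 23.7 ± 2.20 to 2363 ± 562 TPM. Il6 went from 0.31 ± 0.29 to 78.1 ± 26.9 TPM. Serpinb2, a serine protease inhibitor, rose by a log2 fold change of 10.89 (SE 0.51) and Il23a by 8.30 (SE 0.43). Of the 34 cytokine genes, 31 rose, 0 fell and 3 did not pass (32 adjusted over the list alone; adjusted p = 1.3e-20, and adjusted p = 0.039 with an estimated correlation). All 27 NF-kB genes rose, also adjusted over the list alone (adjusted p = 7.8e-36, and adjusted p = 0.013 with an estimated correlation), with Nfkbiz at a log2 fold change of 7.22 (SE 0.19). Immediate-early genes rose at 29 and fell at 3 of 33, the same adjusted over the list alone (adjusted p = 1.2e-19, and adjusted p = 0.0155 with an estimated correlation). Junb rose by 4.22 (SE 0.11).

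NRF2 targets and metallothioneins rose at 12 of 24 and fell at 1, with 11 not passing (14 and 1 adjusted over the list alone; adjusted p = 6.8e-06, and adjusted p = 0.039 with an estimated correlation). Slc7a11 rose by 4.76 (SE 0.19) and the metallothionein Mt2 went from 232 ± 46.6 to 1671 ± 288 TPM. Cd14 rose by 3.93 (SE 0.08), Clec4e by 5.30 (SE 0.15), and Irf1, an interferon regulatory factor, by 4.09 (SE 0.15). Cd83 rose by 3.75 (SE 0.14) and the co-stimulatory receptor Cd40 by 3.66 (SE 0.36). Cell cycle genes fell at 14 of 34 and rose at 3, with 17 not passing (15 and 3 adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.55 with an estimated correlation). Ccne2, a cyclin, fell from 11.2 ± 2.13 to 4.17 ± 0.45 TPM and Plk1, a mitotic kinase, from 17.4 ± 3.01 to 7.65 ± 0.98 TPM. The zinc finger genes Zkscan4 and Zfp128 fell by 4.52 (SE 0.69) and 3.52 (SE 0.30) on the log2 scale, and Arrdc3, an arrestin family gene, by 3.36 (SE 0.28). Adra2a fell by 3.49 (SE 0.50) and Icam5, which lies beside Icam1, fell by 2.67 (SE 0.23). Egr4, an immediate-early gene, and U90926 were at 0 counts in all null naive libraries and were at least 12-fold and at least 11.2-fold higher after exposure.

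TLR and inflammasome genes rose at 16 and fell at 7 of 28 (16 and 8 adjusted over the list alone; adjusted p = 8.5e-04, and adjusted p = 0.14 with an estimated correlation). Heat shock genes rose at 15 and fell at 3 of 23 (16 and 3 adjusted over the list alone; adjusted p = 5.2e-04, and adjusted p = 0.24 with an estimated correlation). MHC class II and co-stimulation genes rose at 11 and fell at 2 of 15 (11 and 3 adjusted over the list alone; adjusted p = 9.5e-05, and adjusted p = 0.18 with an estimated correlation). Glycolysis genes rose at 16 and fell at 2 of 27 (17 and 2 adjusted over the list alone; adjusted p = 1.3e-04, and adjusted p = 0.070 with an estimated correlation), and cholesterol synthesis genes rose at 13 and fell at 3 of 25 (15 and 3 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation), with medians that became -0.05 for both on the log2(TPM + 1) scale. Lysosome genes (17 up and 4 down of 40, the same adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.34 with an estimated correlation) and phagocytic receptors (15 up and 8 down of 31, and 17 and 8 adjusted over the list alone; adjusted p = 0.0157, and adjusted p = 0.34 with an estimated correlation) had medians that became -0.27 and -0.06 on that scale.

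In null mice, adhesion partners and linkers of ICAM-1 rose at 17 and fell at 3 of 29 (18 and 4 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.24 with an estimated correlation), with a median that became -0.06 on the log2(TPM + 1) scale. Alveolar macrophage identity genes rose at 11 and fell at 5 of 30 (12 and 5 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.249 with an estimated correlation), with a median that became -0.19 on that scale. Dendritic cell markers rose at 7 of 13 with 0 lower (7 adjusted over the list alone; adjusted p = 0.0162, and adjusted p = 0.286 with an estimated correlation). Monocyte and interstitial macrophage markers rose at 7 and fell at 1 of 19 (the same adjusted over the list alone; adjusted p = 0.0343, and adjusted p = 0.143 with an estimated correlation). T and NK cell markers rose at 5 of 20 with 0 lower (4 adjusted over the list alone; adjusted p = 0.044, and adjusted p = 0.343 with an estimated correlation). Endothelial and stromal markers rose at 4 of 18 with 0 lower (4 adjusted over the list alone; adjusted p = 0.044, and adjusted p = 0.391 with an estimated correlation), with a median that became -0.07 on the log2(TPM + 1) scale. The lists of interferon-stimulated genes (8 up and 7 down of 37; adjusted p = 0.661), lipid handling (8 up and 5 down of 30; 0.794) and NADPH oxidase genes (4 up and 1 down of 10; 0.175) did not pass, with the same counts adjusted over the list alone. Neither did B cell markers (0 of 8, also adjusted over the list alone; 0.633), genes beside Icam1 (7 up and 16 down of 37, and 8 and 17 adjusted over the list alone; 0.216) or known strain differences (4 up and 7 down of 25, the same adjusted over the list alone; 0.665).

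Epithelial markers rose at 14 of 25 and fell at 1, with 10 not passing (the same adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.34 with an estimated correlation), with Scgb1a1 at 205 ± 39.9 TPM before and 440 ± 53.9 TPM after exposure. Of 9 erythroid and platelet markers 1 rose, the platelet integrin gene Itga2b (1.35, SE 0.35), and 8 did not pass (1 rose adjusted over the list alone; adjusted p = 0.39). Neutrophil markers rose at 7 of 14 and fell at 1 (the same adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.24 with an estimated correlation), with Csf3r lower by a log2 fold change of -0.51 (SE 0.07). In all, 9180 genes differed, 4387 higher and 4793 lower, 3535 with an absolute log2 fold change of at least 1. Camera called 20 of 27 lists, 4 of them also with an estimated correlation. On the log2(TPM + 1) scale the median of all genes moved to -0.33 and 19.6% of calls were higher against 47.8%, and with covariates for neutrophil and lymphocyte RNA 3526 genes differed. Ccne2 (-0.73), Adra2a (-2.56) and Itga2b (0.22) no longer passed with those covariates, and Itga2b (0.97) did not with covariates for epithelial and red cell RNA either, of which it is a part. Neutrophil list levels were at most 1.58 log2 CPM in naive null and at least 2.05 in exposed null libraries. Cell mix and adjustment for the response itself thus cannot be told apart in the losses with that covariate.

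The responses of both genotypes ran together across genes. Over the 10793 genes called in either genotype, log2 fold changes correlated with a Pearson coefficient of 0.802 and a Spearman coefficient of 0.905, with genes that are not independent replicates. Both genotypes called 6632 genes, and 6623 of them had the same sign. Independent lists of these sizes would share 880 higher and 967 lower genes, against 3098 and 3525 observed.

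**Figure D3:**
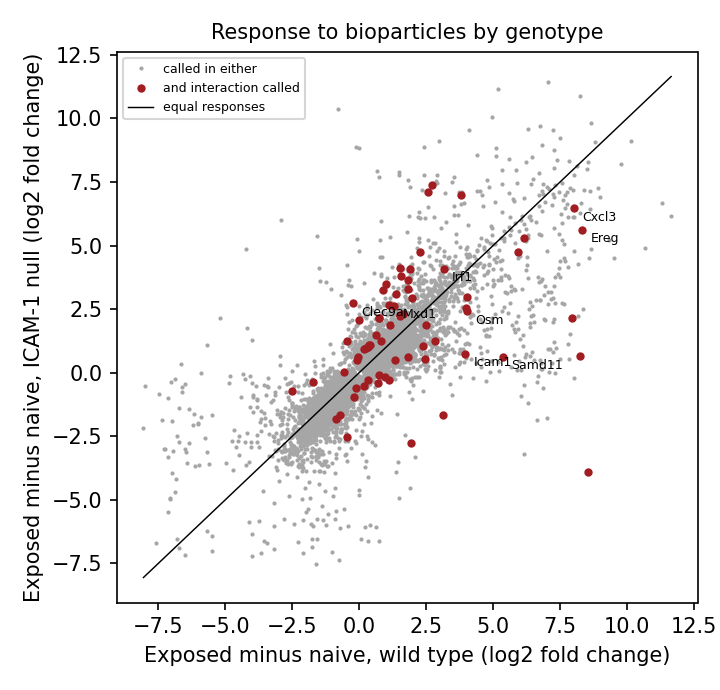
Log2 fold change on exposure in null (vertical axis) against wild type (horizontal axis) for the 10793 genes called in either; red points are those among them with a called interaction, and the line marks equal responses. Pearson's coefficient was 0.802, and Icam1 and Samd11 lie below the line.

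The comparison of naive null with naive wild type mice asked which transcripts differ with genotype before any exposure. Several genes were close to absent in 1 genotype. Aass, an enzyme of lysine breakdown (chromosome 6, 23072172 to 23132985), stood at 83.1 ± 11.4 TPM in null and 0.48 ± 0.47 TPM in wild type libraries (log2 fold change 7.28, SE 0.34, adjusted p = 2.7e-12). Spic, a transcription factor of red pulp macrophages, stood at 16.1 ± 1.33 against 0.22 ± 0.24 TPM. The transporter genes Slc22a4 and Slc10a6 were higher in null by 5.91 (SE 0.34) and 6.92 (SE 0.52). The acute phase gene Orm2 was higher by 4.39 (SE 0.40). In the other direction, Skint3 (0.16 ± 0.10 against 13.5 ± 2.39 TPM), the coronin gene Coro2b (-5.49, SE 0.20) and Ppfia4 (-5.32, SE 0.21) were lower in null. So were Kazn (-4.93, SE 0.30), C77080 (-4.51, SE 0.17) and Adamts2, a procollagen protease (-4.39, SE 0.24).

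H2-Aa stood at 427 ± 86.7 against 74.9 ± 14.1 TPM, H2-Ab1 at 592 ± 109 against 121 ± 20.3 TPM and Cd74, the invariant chain, at 1271 ± 226 against 276 ± 45.3 TPM. Of the 15 genes in the MHC class II and co-stimulation list, 7 were higher, 2 lower and 6 did not pass (8 and 2 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.295 with an estimated correlation). Phagosome and lysosome genes were higher at 11 of 40, with 0 lower and 29 not passing (23 adjusted over the list alone; adjusted p = 5.9e-15, and adjusted p = 0.067 with an estimated correlation). They included the protease Ctsk (1699 ± 246 against 628 ± 79.3 TPM), Gpnmb (1.19, SE 0.09) and lysozyme Lyz2 (29860 ± 968 against 21130 ± 776 TPM). Among scavenger receptors, Marco was higher (1844 ± 206 against 478 ± 64.2 TPM) and Msr1 lower (1.86 ± 0.91 against 13.1 ± 1.49 TPM). Their list had 8 higher and 3 lower of 31 (10 and 6 adjusted over the list alone) and did not pass (adjusted p = 0.25).

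Cell cycle genes were higher at 16 of 34, with 0 lower and 18 not passing (25 adjusted over the list alone; adjusted p = 9.5e-13, and adjusted p = 0.32 with an estimated correlation). The mitotic genes Birc5, Mki67 and Hmmr were higher: Birc5 by 0.68 (SE 0.11), Mki67 by 0.52 (SE 0.10) and Hmmr by 0.92 (SE 0.19). NRF2 targets were higher at 5 of 24 with 0 lower (8 adjusted over the list alone; adjusted p = 3.7e-06, and adjusted p = 0.067 with an estimated correlation). Among them were Slc7a11 at 9.48 ± 2.48 against 3.13 ± 0.69 TPM and Srxn1 at 0.58 (SE 0.10). Heat shock and unfolded protein response genes were higher at 4 of 23 with 0 lower (6 adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.48 with an estimated correlation). Their members included Hspa1a at 1.84 (SE 0.44) and Trib3 at 1.37 (SE 0.26).

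Csf3r, the G-CSF receptor gene, was higher in null by a log2 fold change of 1.73 (SE 0.08), the chemokine receptor Cxcr2 by 1.46 (SE 0.22) and S100a8 by 1.38 (SE 0.28). These were the 3 higher of 14 neutrophil markers (0 lower; 3 and 2 adjusted over the list alone; adjusted p = 0.14). Cytokine genes were higher at 8 and lower at 2 of 34 (14 and 6 adjusted over the list alone; adjusted p = 0.15). The chemokine Ccl22 was higher by 1.24 (SE 0.14) and Ccl9 stood at 62.2 ± 18.2 against 19.9 ± 6.37 TPM. Klf2, a Krüppel-like factor, differed by a log2 fold change of -1.02 (SE 0.17). Alveolar macrophage identity genes were higher at 7 and lower at 2 of 30 (11 and 7 adjusted over the list alone; adjusted p = 0.14), with the ribonuclease Ear6 at 2.78 (SE 0.33), Epcam at 1.05 (SE 0.14) and Car4, a carbonic anhydrase, at -1.11 (SE 0.13). Vcam1, an integrin ligand, stood at 1.46 ± 0.60 against 0.19 ± 0.13 TPM. Icam4, which starts just past the end of Icam1 (chromosome 9, 20940669 to 20941891), stood at 6.36 ± 1.63 against 1.75 ± 1.05 TPM. The erythropoietin receptor gene Epor stood at 18.8 ± 2.96 against 5.18 ± 0.55 TPM. None of 9 erythroid and platelet markers passed (also adjusted over the list alone; adjusted p = 0.28).

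In all, 1406 genes differed, 883 higher in null and 523 lower, 503 with an absolute log2 fold change of at least 1. On the log2(TPM + 1) scale 45.2% of calls were higher against 62.8%. Without wild type naive libraries 1, 2 and 3, which leaves a single library assumed to vary like the others, 321 genes differed, 307 of them among the 1406. Calls were lost for Mki67 (log2 fold change 0.42, SE 0.16), Birc5 (0.58, SE 0.18), Hmmr (0.76, SE 0.30), Ccl9 (1.25, SE 0.42), Cxcr2 (1.19, SE 0.34), S100a8 (1.66, SE 0.49), Epcam (0.89, SE 0.24), Icam4 (1.88, SE 0.50), Klf2 (-0.82, SE 0.23), Srxn1 (0.53, SE 0.17), Trib3 (1.63, SE 0.42), Hspa1a (1.5, SE 0.79) and Wdfy1 (0.73, SE 0.18). With covariates for neutrophil and lymphocyte RNA 840 genes differed, without S100a8 (1.08), itself part of a covariate, and Hspa1a (1.71), which limma-voom with sample weights lost too (1.69). Within 10 Mb of Icam1 15 of 152 tested genes differed by genotype in naive mice, against 1390 of 20348 elsewhere, an odds ratio of 1.49 (95% interval 0.811 to 2.56, Fisher's exact test, two-sided p = 0.145), and within 20 Mb 25 of 250 against 1380 of 20250 (odds ratio 1.52, 95% interval 0.959 to 2.31, same test, p = 0.0575). Of 37 genes in the list beside Icam1, 3 were higher and 2 lower in null, the same adjusted over the list alone. Camera gave that list an adjusted p = 0.98, and an adjusted p = 0.986 with an estimated correlation. Known strain differences were higher in null at 3 and lower at 4 of 25, with 18 not passing (3 and 5 adjusted over the list alone; adjusted p = 0.546, and adjusted p = 0.781 with an estimated correlation). Camera tests a shift of a list in 1 direction, so it cannot show a list that differs both ways. Of all tested genes 6.86% differed by genotype in naive mice.

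The comparison of exposed null with exposed wild type mice asked which transcripts differ with genotype after exposure to particles. Part of the genotype differences of naive mice were seen again, and Aass stood at 63.4 ± 5.12 against 1.35 ± 0.20 TPM and Spic at 26.1 ± 4.58 against 0.82 ± 0.41 TPM. Slc22a4 and Orm2 were higher by 4.50 (SE 0.28) and 3.70 (SE 0.33). Skint3 (-6.23, SE 0.42), Coro2b (-5.17, SE 0.20), C77080 (-4.63, SE 0.17) and Kazn (-4.37, SE 0.30) were lower. Lyg1, a lysozyme G-like gene, was at 0 counts in every exposed wild type library and at least 2.97-fold higher in null. Of the calls in naive and in exposed mice 811 were shared, 804 of them with the same sign. Another 595 were called in naive mice alone and 927 in exposed mice alone. Of the shared calls, 280 differed at least 2-fold in both, 179 higher and 101 lower.

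Among cytokines, both directions were seen. Osm, a cytokine of the IL-6 family, stood at 38.8 ± 4.95 TPM in null against 194 ± 50.5 TPM in wild type libraries (log2 fold change -2.30, SE 0.17, adjusted p = 4.3e-09). Its relative Lif stood at 12.9 ± 2.37 against 53.0 ± 17.7 TPM. Csf3, which encodes G-CSF, stood at 20.2 ± 5.35 against 6.94 ± 1.36 TPM. The list had 4 members higher, 5 lower and 25 not passing (5 and 6 adjusted over the list alone; adjusted p = 0.72). NF-kB genes were higher at 7 of 27 with 0 lower (7 adjusted over the list alone; adjusted p = 2.0e-04, and adjusted p = 0.44 with an estimated correlation). Ikbke, an IkB kinase relative, stood at 62.5 ± 15.8 against 24.7 ± 7.13 TPM.

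Cell cycle genes had 1 higher and 1 lower of 34 (1 lower adjusted over the list alone; adjusted p = 0.645). Heat shock and unfolded protein response genes had 1 higher of 23 (1 adjusted over the list alone; adjusted p = 0.172).

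Cd74 was higher by 2.30 (SE 0.16) and H2-Ab1 by 2.18 (SE 0.16). Their list had 5 higher and 1 lower of 15 (6 and 2 adjusted over the list alone; adjusted p = 5.2e-04, and adjusted p = 0.33 with an estimated correlation). Phagosome and lysosome genes were higher at 11 of 40 with 0 lower (15 adjusted over the list alone; adjusted p = 2.7e-07, and adjusted p = 0.22 with an estimated correlation). Gpnmb was higher by 0.78 (SE 0.08) and Lyz2 by 0.51 (SE 0.06). NRF2 targets were higher at 5 and lower at 1 of 24 (7 and 1 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.33 with an estimated correlation). Cholesterol synthesis genes were lower at 3 of 25 with 0 higher (3 adjusted over the list alone; adjusted p = 3.7e-04, and adjusted p = 0.44 with an estimated correlation). Among them were the sterol carrier gene Stard4 (-0.34, SE 0.08) and the synthase gene Hmgcs1 (-0.32, SE 0.08). Marco was higher (1.77, SE 0.17) and Msr1 lower (-2.97, SE 0.27). Csf3r was higher by 1.78 (SE 0.08), Vcam1 by 2.27 (SE 0.38), Icam4 by 1.53 (SE 0.33) and Epor by 1.64 (SE 0.20). The complement receptor gene Vsig4 was higher by 3.04 (SE 0.61) and Dppa3, a germ cell gene, differed by -4.40 (SE 0.89).

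Epithelial markers were lower at 8 of 25, with 0 higher and 17 not passing (13 adjusted over the list alone; adjusted p = 2.6e-09, and adjusted p = 0.22 with an estimated correlation). Scgb1a1 stood at 440 ± 53.9 against 1266 ± 735 TPM. The surfactant genes Sftpa1 and Sftpb differed by -1.02 (SE 0.17) and -0.73 (SE 0.18). Erythroid and platelet markers were lower at 5 of 9, with 0 higher (5 lower and 1 higher adjusted over the list alone; adjusted p = 3.1e-04, and adjusted p = 0.22 with an estimated correlation). Hba-a1, an alpha globin, stood at 65.2 ± 26.6 against 398 ± 259 TPM and Hbb-bs at 59.1 ± 27.9 against 418 ± 280 TPM. Globin copies such as Hba-a1 and Hba-a2 are near identical and may share reads. Monocyte and interstitial macrophage markers were lower at 2 and higher at 1 of 19 (3 and 1 adjusted over the list alone; adjusted p = 0.0265, and adjusted p = 0.22 with an estimated correlation). Fn1, fibronectin, stood at 51.8 ± 19.5 against 255 ± 71.8 TPM, and the chemokine receptor Ccr2 differed by -0.80 (SE 0.20). T and NK cell markers were lower at 2 of 20 with 0 higher (7 lower and 1 higher adjusted over the list alone; adjusted p = 2.0e-04, and adjusted p = 0.22 with an estimated correlation). Those were the adhesion receptor Cd2 (163 ± 21.6 against 317 ± 16.5 TPM) and perforin, Prf1 (49.3 ± 9.39 against 69.1 ± 13.8 TPM). Neutrophil markers were higher at 4 and lower at 3 of 14 (the same adjusted over the list alone; adjusted p = 0.295). Myeloperoxidase, Mpo, was at 0 counts in every exposed wild type library and at least 3.87-fold higher in null.

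**Figure D4:**
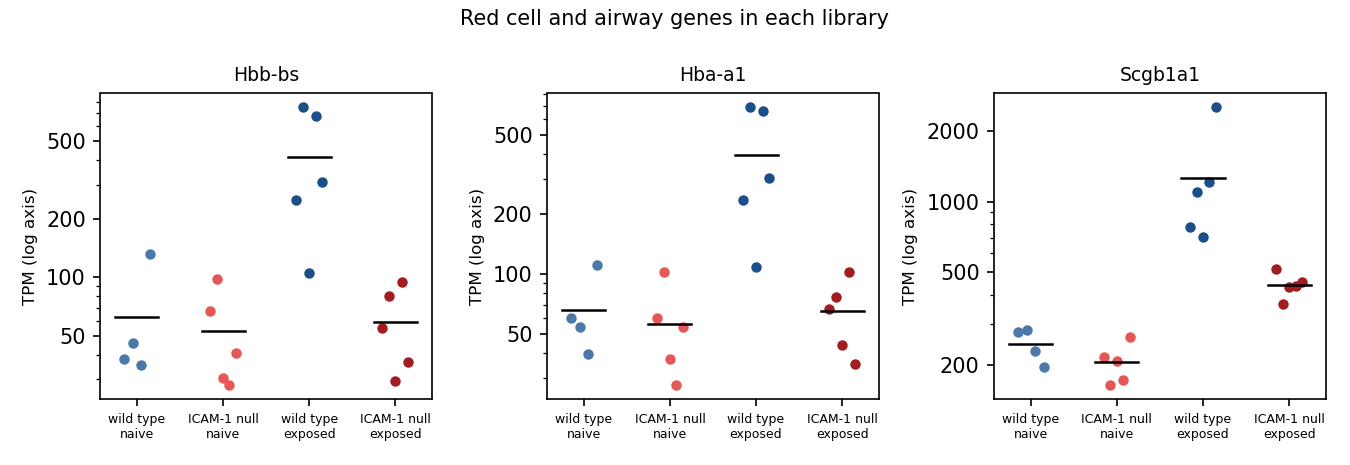
Hbb-bs, Hba-a1 and Scgb1a1 in TPM, on log axes, in each library by group; points are libraries and bars are group means. Exposed wild type libraries held 105 to 748 TPM of Hbb-bs and exposed null libraries 29.3 to 94.3 TPM.

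In all, 1738 genes differed, 909 higher in null and 829 lower, 555 with an absolute log2 fold change of at least 1. With covariates for epithelial and red cell RNA 386 genes differed (with those for neutrophil and lymphocyte RNA 1126, without Sftpb at -0.70 and Prf1, itself part of a covariate, at -0.36). Of the calls lost with the former, Vcam1 (2.37), Vsig4 (3.74), Icam4 (1.83), Ccr2 (-0.84) and Prf1 (-0.46) had log2 fold changes as large as before or larger, and Ikbke (1.32), Epor (1.25), Stard4 (-0.30), Hmgcs1 (-0.31) and Dppa3 (-3.47) smaller ones. Scgb1a1 (-1.08), Sftpa1 (-0.69), Sftpb (-0.30) and the globins, which reversed, are part of those covariates, so their losses follow by construction. Mpo was lost too, and limma-voom with sample weights lost Ccr2 (-0.78). Without the 3 exposed libraries that stood apart, the calls of Ccr2 (-0.83), Hmgcs1 (-0.25), Icam4 (1.36), Stard4 (-0.32) and Sftpb (-0.64) were lost. Prf1 no longer passed without exposed wild type library 1 (-0.40) or 2 (-0.36) or exposed null library 1 (-0.42), 2 (-0.36) or 3 (-0.42), nor with only the 2 groups compared (-0.45), and Hmgcs1 no longer passed without exposed wild type library 5 (-0.28). Within 10 Mb of Icam1 18 of 152 genes differed, against 1719 of 20348 elsewhere (odds ratio 1.46, 95% interval 0.835 to 2.40, Fisher's exact test, two-sided p = 0.142). Within 20 Mb the share was higher than elsewhere, with 33 of 250 against 1704 of 20250 (odds ratio 1.66, 95% interval 1.11 to 2.40, Fisher's exact test, two-sided p = 0.0113). Of 37 genes in the list beside Icam1, 3 were higher and 6 lower in null, the same adjusted over the list alone. Camera gave that list an adjusted p = 0.66, and an adjusted p = 0.873 with an estimated correlation. Known strain differences were higher in null at 3 and lower at 4 of 25, with 18 not passing (3 and 5 adjusted over the list alone; adjusted p = 0.509, and adjusted p = 0.845 with an estimated correlation). As in naive mice, camera cannot show differences that go both ways. Of all tested genes 8.48% differed by genotype in exposed mice.

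**Figure D5:**
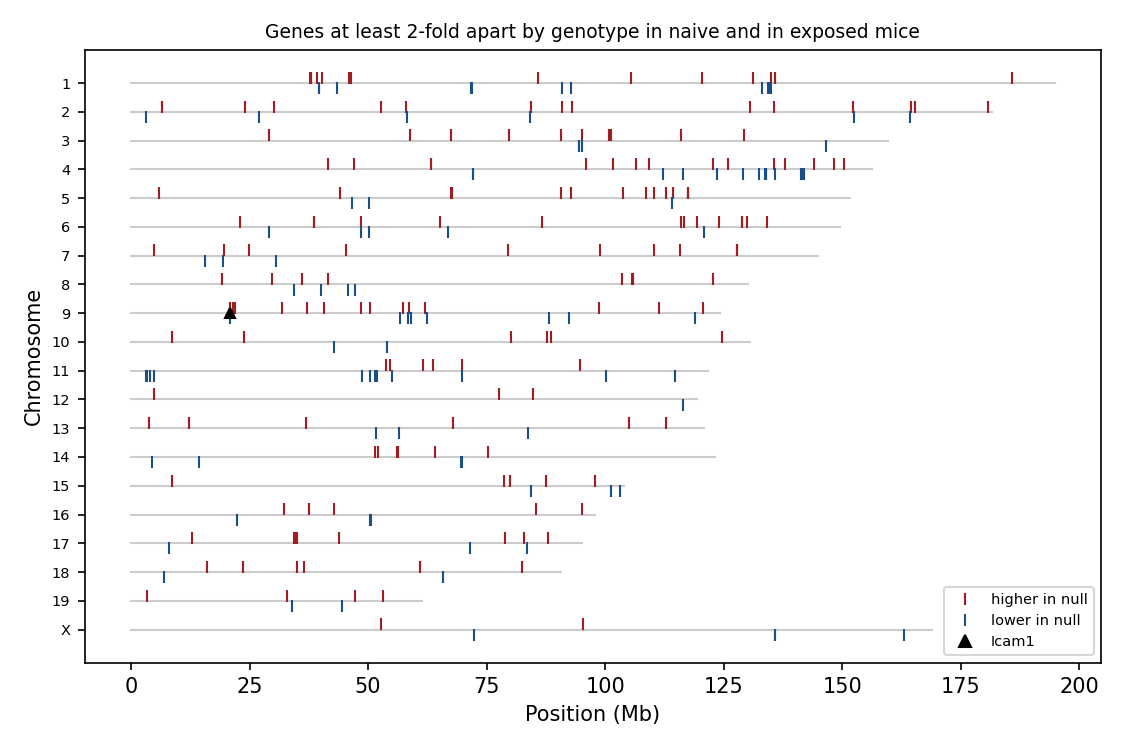
Positions, in Mb along each chromosome, of the 280 genes that differed at least 2-fold by genotype in the same direction in naive and in exposed mice; red ticks are higher in null and blue ticks lower, and the triangle is Icam1. Chromosome 4 held 32 of them, 2.77% of its tested genes, against 1.37% of all tested genes.

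The interaction asked which genes responded to exposure to a different degree in null mice. Icam1 itself rose less in null, by -3.21 on the log2 scale (SE 0.25, adjusted p = 6.6e-07). Pts, an enzyme of tetrahydrobiopterin synthesis (chromosome 9, 50432917 to 50440024), went from 44.1 ± 4.97 to 27.7 ± 5.64 TPM in wild type and from 42.9 ± 6.77 to 67.7 ± 7.21 TPM in null mice, an interaction of 1.73 (SE 0.14, adjusted p = 7.8e-07). Samd11 went from 0.57 ± 0.46 to 17.3 ± 3.44 TPM in wild type and from 3.44 ± 0.72 to 4.10 ± 1.40 TPM in null mice (-4.74, SE 0.55). Cdc42bpg, a kinase that binds Cdc42, went from 15.8 ± 0.27 to 26.5 ± 5.31 TPM and from 15.9 ± 0.61 to 79.9 ± 21.4 TPM (1.56, SE 0.20). Mxd1, a partner of MAX, went from 20.8 ± 3.07 to 39.6 ± 6.12 TPM and from 17.5 ± 3.94 to 84.3 ± 15.2 TPM (1.33, SE 0.20).

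Among cytokines and growth factors, 3 of 34 list members had a lower response in null and 0 a higher one (13 lower and 4 higher adjusted over the list alone; adjusted p = 0.0047, and adjusted p = 0.68 with an estimated correlation). The mean log2 fold change of that list, null against wild type, was 0.35 in naive and -0.06 in exposed mice. Osm had a difference of -1.61 (SE 0.24), Cxcl3 of -1.55 (SE 0.26) and Ccl22 of -1.04 (SE 0.19), and the EGF family ligand Ereg, outside that list, of -2.70 (SE 0.50). Irf1 (0.93, SE 0.19), the phosphatase gene Dusp5 (0.96, SE 0.14) and the glycolysis regulator Pfkfb3 (0.71, SE 0.14) rose more in null. The X-linked ubiquitin ligase gene Mid1 (2.59, SE 0.46), the complement gene C4a (2.38, SE 0.37), Proz (1.75, SE 0.26) and the dendritic cell receptor gene Clec9a (2.96, SE 0.54) responded higher in null. Fstl1 (-1.92, SE 0.39), Nectin1 (-1.40, SE 0.25), Slc7a11 (-1.19, SE 0.25) and Clec4e (-0.86, SE 0.18) had lower ones.

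By list, cell cycle genes had a lower response in null, with 0 members called over all genes and 18 of 34 lower adjusted over the list alone (camera adjusted p = 2.6e-15, and adjusted p = 0.683 with an estimated correlation). Their mean log2 fold change, null against wild type, was 0.40 in naive and -0.02 in exposed mice. The lower response thus went with a higher naive level in null, not with a lower level after exposure. NF-kB genes had a higher one with 0 of 27 called, also adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.683 with an estimated correlation). The lists of cholesterol synthesis (adjusted p = 8.0e-04; 0 of 25 called), epithelial (8.0e-04; 0 of 25, and 3 lower adjusted over the list alone), lysosome (0.00505; 0 of 40), NRF2 (0.0205; 1 lower of 24, and 3 adjusted over the list alone) and erythroid genes (0.0448; 0 of 9, and 5 lower adjusted over the list alone) had lower ones. Each of these lists had an adjusted p = 0.68 with an estimated correlation. By the same mean, lysosome and NRF2 genes were higher in null in naive mice (0.25 and 0.34) and less so in exposed mice (0.15 and 0.14). Cholesterol synthesis, epithelial and erythroid genes stood at 0.02, -0.18 and -0.41 in naive mice. In exposed mice those 3 means were lower, at -0.17, -0.64 and -1.87. In all, 68 genes passed, 37 with a higher and 31 with a lower response in null, and 2019 had an unadjusted p under 0.05. Without wild type naive libraries 1, 2 and 3, 10 genes passed, 8 of them among the 68. Calls lost there were those of Ereg (-1.82), Osm (-1.59), Cxcl3 (-1.27), Fstl1 (-2.03), Nectin1 (-1.53), Ccl22 (-0.98), Slc7a11 (-0.84), Clec4e (-0.52), Mid1 (2.89), C4a (2.32), Proz (1.70), Clec9a (3.14), Irf1 (0.82), Dusp5 (0.86) and Pfkfb3 (0.79). Covariates for epithelial and red cell RNA ended the calls of Ereg (-1.99), Cxcl3 (-1.30), Fstl1 (-1.29), Nectin1 (-1.27), Slc7a11 (-0.96), Ccl22 (-0.88), Clec4e (-0.58), Irf1 (1.12) and Pfkfb3 (0.67). Those for neutrophil and lymphocyte RNA ended the calls of Slc7a11 (-1.10), Fstl1 (-1.65) and Clec4e (-0.74). With limma-voom and sample weights Ereg (-3.01), Fstl1 (-1.87), Cxcl3 (-1.66), Nectin1 (-1.41), Slc7a11 (-1.20), Clec4e (-0.90), Mid1 (2.46) and Irf1 (0.88) did not pass. Of the 19 libraries left out in turn, 15 ended the call of Slc7a11 (-1.23 to -1.06), 14 those of Clec4e (-0.89 to -0.78) and Irf1 (0.86 to 0.96), 9 those of Fstl1 (-2.05 to -1.79) and Pfkfb3 (0.67 to 0.73) and 3 that of Ereg (-2.61 to -2.49). Of the genes named, Icam1, Samd11, Pts, Cdc42bpg and Mxd1 passed under every alternative run. Leaving out single libraries gave 34 (without wild type naive library 1) to 82 genes (without wild type naive library 4), with 34 without wild type naive library 2, 37 without wild type naive library 3, 45 without null naive library 1 and 43 without null naive library 2 or 4, exposed wild type library 4 or exposed null library 2.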

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

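The tests of how genotype differences lie along the chromosomes (except that of shared reads), both tests of carried reads, the test of the altered locus and both tests of red cell and epithelial RNA, thinning and covariates included, were chosen only after the result was seen.

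Genotype differences of at least 2-fold and the same sign in naive and exposed mice (280 genes) lay close together in places. In 132.5 to 142.5 Mb of chromosome 4 they were 13 of 172 tested genes (including Kazn). In 37.85 to 47.85 Mb of chromosome 1 they were 11 of 71 (including Lyg1). These are 7.56% and 15.5%, against 1.37% of all tested genes. Both windows were picked for holding the most such genes, so shares above the whole follow by construction. Reads shared by overlapping or like-named neighbours were argued against as the whole cause. Without such neighbours adjacent pairs were still 4.97 times as frequent as at shuffled positions (14 pairs against a mean of 2.82, permutation p = 1e-04, the smallest that 10000 shuffles can give). Reads shared between other neighbours, or between copies with unlike names, were not tested. Lower depth of wild type naive libraries 1, 2 and 3 was argued against for genes that stayed in the test. After thinning to the smallest library total on counts divided by 4, 258 of the 280 genes were still tested. Of these, 241 (93.4%) were called in both comparisons. The others were no longer tested, so depth remains open for them. All 280 had also been called in exposed mice, a comparison without those 3 libraries, so a high share kept follows in part by construction. The 595 genes called in naive mice alone were not put to this test. For DNA of a donor strain kept outside the Icam1 region, the test on adjacent genes met the outcome stated against it, a ratio of 6.04 below the 11 of as many exposure genes, but cannot decide, because exposure genes also lie side by side (6.68 against 4.97 without overlapping or like-named pairs). A test chosen after that failure counted pairs 1 to 10 Mb apart. They lay at 1.36 times the shuffled frequency (421 against 310, permutation p = 0.002) and at 1.04 times among exposure genes, so donor DNA may contribute. Of 25 known strain differences 3 were higher and 4 lower in null, in naive as in exposed mice. Of all tested genes, 6.86% differed by genotype in naive and 8.48% in exposed mice. On exposure in wild type 7 of the 25 rose and 8 fell, where 40.2% of all tested genes differed. An effect of ICAM-1 loss may contribute as well, which was not tested, and sequence variants were not analysed here.

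Icam1 counts remained in null libraries. Carriage of wild type RNA or reads of the same exposure was argued against: the 95% upper bound of the rise in null was 1.10 (log2), against a rise of 3.97 in wild type. Carriage from a pool of all libraries was argued against as well, since Icam1 in naive null libraries kept 3.16% of its mean over all libraries and 24 genes kept less, among them Il23a (0.806%), Cxcl1 (1.38%) and Tnf (1.64%). A transcript from the altered Icam1 locus, which gene totals cannot show by exon, may remain; the neighbour Icam4 was higher in naive null mice by 1.90 (log2), which does not decide it, so a truncated product and reads assigned from the neighbour cannot be told apart here.

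Red cell and epithelial RNA was lower in exposed null than in exposed wild type libraries. All of the 19 list members with at least 10 TPM in exposed wild type, 100% of them, had lower estimates in null, 10 of them called. Members were kept by their level in exposed wild type, so this restates the pattern, and less RNA of those cells in the pellets and lower expression cannot be told apart. That these cells set the other genotype calls taken as a whole was argued against. With the levels of both lists as covariates, the median called gene kept 97.0% of its fold, and 1712 of 1725 kept their sign. However, 811 of the exposed calls were also made in naive mice, where neither list passed (camera adjusted p = 0.19 and 0.28). The 927 genes called in exposed mice alone were not tested apart, so the test cannot decide for them. Of those 1725 genes 356 kept their call, as the median SE went from 0.129 to 0.225. Whether the loss of ICAM-1 changed leakage of blood or airway cells, or the lavage differed between mice, was not tested.

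Other groupings of the same libraries were tried, 100 per comparison with the real grouping included, out of 15876 possible for the interaction. They put libraries of unlike exposure or genotype into the same group, which widens the spread there. Fewer calls then follow in part by construction, so the groupings cannot exclude chance. For exposure in wild type 8245 genes were called and at most 5456 by another grouping, and 1 grouping, the real one, gave as many. The same number, 1, held for exposure in null mice (9180 against at most 1619), for genotype in naive mice (1406 against at most 390), for genotype in exposed mice (1738 against at most 124) and for the interaction (68 against at most 20).

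Single libraries far from the rest of their group were found in 9 of 300 groups of values tested (3%), where chance alone gives about 1 in 20. Scgb1a1 stood at 2525 TPM in exposed wild type library 5, against 707 to 1215 in the others, and Sftpb at 13.4 TPM in exposed wild type library 3, against 20.5 to 22.1. Hbb-bs stood at 131 TPM in naive wild type library 4, against 35.5 to 46.3. Slc22a4 stood at 34.8 TPM in naive null library 2, against 21.8 to 25.4, and Birc5 at 52.5 TPM in naive null library 1, against 36.3 to 40.4. Skint3 stood at 9.95 TPM in naive wild type library 3, against 14.2 to 15.1, and Klf2 at 34.6 TPM in naive wild type library 1, against 20.0 to 20.8. In exposed wild type library 2, Vcam1 stood at 0.76 TPM, against 1.36 to 1.38, and Clec9a at 3.65 TPM, against 1.85 to 2.34.

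Differences between the responses of both genotypes, tested as an interaction, were found for 20 named genes. Lower responses in null (log2) were those of Samd11 (-4.74), Icam1 (-3.21), Ereg (-2.70), Fstl1 (-1.92), Osm (-1.61), Cxcl3 (-1.55), Nectin1 (-1.40), Slc7a11 (-1.19), Ccl22 (-1.04) and Clec4e (-0.86). Higher responses in null were those of Clec9a (2.96), Mid1 (2.59), C4a (2.38), Proz (1.75), Pts (1.73), Cdc42bpg (1.56), Mxd1 (1.33), Dusp5 (0.96), Irf1 (0.93) and Pfkfb3 (0.71).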

How the results depend on the processing

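The tests with counts divided by 4, thinning, left-out shallow or distant libraries and epithelial and erythroid covariates were chosen only after the result was seen. Of 5801 alternative values for 167 named results, 5606 kept direction and call, 189 (53 results) lost the call and 6 reversed. The minimum absolute log2 fold change of 1 is left out of this tally. Refits without a library of a group outside the comparison are in it, and these can change little. The Icam1 difference in naive mice kept its call in all alternatives, and leaving out single libraries moved it between -3.29 and -2.99. Leaving out single libraries gave 7393 to 8355 genes for exposure in wild type, 8439 to 9290 in null, 1072 to 1499 for genotype in naive and 1441 to 1709 in exposed mice, 34 to 82 for the interaction, and 5 to 12 gene lists for the interaction. Lower depth of wild type naive libraries 1, 2 and 3 limits what the naive comparison can show for low genes.

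Requiring an absolute log2 fold change of at least 1 gave 3298, 3535, 503, 555 and 42 genes for exposure in wild type, exposure in null, genotype in naive mice, genotype in exposed mice and the interaction, fewer by construction. Neutrophil and lymphocyte covariates gave 1481, 3526, 840, 1126 and 40. In both genotypes neutrophil list levels separated exposed from naive libraries, so for exposure cell mix and the response itself cannot be told apart. Without wild type naive libraries 1, 2 and 3, with fewer samples, exposure in wild type gave 4253, genotype in naive mice 321 and the interaction 10. Epithelial and erythroid covariates gave 2500 for exposure in wild type, 386 for genotype in exposed mice and 35 for the interaction. With them Hba-a1 and Hbb-bs reversed for exposure in wild type, to -0.29 and -0.51, and Hba-a1, Hba-a2, Hbb-bs and Hbb-bt reversed for genotype in exposed mice, to 0.21, 0.084, 0.43 and 0.53, by construction, as globins are part of a covariate. The interaction gave 38 genes with no filter, 41 after thinning, 266 with DESeq2 (40.6% higher against 54.4%) and 111 with limma-trend on log2(TPM + 1) (68.5% higher). It gave 80% higher without wild type naive libraries 1, 2 and 3 and with epithelial and erythroid covariates, and 72% without the 3 distant exposed libraries. Except where stated above, the cause was not tested.

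With an estimated correlation camera called 5 and 4 lists for exposure in wild type and null and 0 for both genotype comparisons and the interaction, against 20, 20, 5, 9 and 8. The self-contained test fry called 9 lists for genotype in naive mice and 0 for the interaction, where camera called 8. The odds ratio near Icam1 in exposed mice passed with a window of 20 Mb, at 1.66. Over all tested genes the responses correlated at 0.732 (Pearson) and 0.768 (Spearman).

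With the replicate block the counts were 7808, 9037, 1365, 1649 and 52. For the interaction 40 of the 52 were among the 68 of the main fit, and the calls of Clec4e, Mid1 and Slc7a11 were lost. Across 27 pairs of same-numbered libraries, the correlations of deviations lay between -0.05 and 0.07, none above 0.1. In 6 pairs the same number was the best match, among them 1, 2 and 3 of exposed wild type with exposed null. No clear pairing by number was seen, but with so few libraries per group a shared day or litter cannot be excluded.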

Other observations

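The 280 genes that differed by genotype at least 2-fold in naive and exposed mice were also dense in 131.2 to 141.2 Mb of chromosome 1, where 8 of 113 tested genes were in the set (7.08%). Ikbke and Ppfia4 lie there. In 48.84 to 58.84 Mb of chromosome 11, where Adamts2 and Slc22a4 lie, 7 of 136 were in the set (5.15%), and in 108.7 to 118.7 Mb of chromosome 5, 8 of 152 (5.26%). Their windows were chosen after the values were seen. Of the 280 genes, 27 were annotated as pseudogenes (9.64%), against 11.8% of tested genes.

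The antigen presentation gene Cd74 stood at 276, 1271, 444 and 2140 TPM in naive wild type, naive null, exposed wild type and exposed null libraries. Marco stood at 478, 1844, 589 and 1963 TPM in the same order, and Car4 at 975, 436, 2792 and 1724 TPM. Fn1 stood at 98.3, 32.7, 255 and 51.8 TPM.

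Mitochondrial transcripts made up 2.78% to 6.81% of counts per library, and the 10 most abundant genes 8.05% to 10.2%. Between 21644 and 24475 genes were above 0 per library. No further hypothesis was tested.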
